A study of Homo sapiens with 10 samples.

How the data were processed

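RNA sequencing libraries of A549 cells were compared. A549 is an established lung adenocarcinoma line without functional SMARCA4, the ATPase of the BAF chromatin remodelling complexes. There were 6 libraries of cells in which the SMARCA4 mutation had been corrected, called rescue, and 4 libraries of uncorrected cells, called null. Per the labels' protocols, total RNA was isolated with the Ambion mirVana kit and libraries were made with the Illumina TruSeq Stranded Total RNA kit. Spike-in RNAs of the sequin set were present in the counted annotation.

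The deposited files hold raw counts of fragments, 1 file per library, made by the authors with featureCounts 1.5.1 per the file headers. Primary alignments with both ends mapped were counted on exons by gene identifier, reverse-stranded, with a minimum overlap fraction of 0.5 and a maximum pair distance of 10000 bases. A gene length in bases, the summed exon length, stands beside each count per the file headers. The submitters' processing notes also name Cufflinks 2.2.1, Subread and the builds GRCh38 and hg38. The aligner was not given in the sources used here. Because primary alignments can include reads with several matches, values of genes with near-identical copies are uncertain.

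Each file held 58037 genes and 78 spike-in RNAs. Spike-ins were left out of library totals and of the gene test, and were fitted by themselves. Gene symbols came from GENCODE 29, matched by identifier without version, which named 57433 genes. Gene-assigned fragments ranged from 3117497 to 14308570 per library. On these totals, before further scaling, 1 fragment stood for between 0.0699 and 0.321 CPM, fragments scaled to a common library total. CPM values used library totals scaled by trimmed mean of M values (TMM) factors.

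Genes were kept by filterByExpr of edgeR 4.0.16 with its minimum count of 10 and minimum total of 15, which left 14467 genes. Rescue and null were compared with the robust quasi-likelihood F test of edgeR, two-sided, with no covariate, since the labels give no batch, clone or pairing. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 28.2%. SMARCA4 and SMARCA2 were also compared by an exact two-sided permutation test on log2 CPM over the 210 splits of 10 libraries into 6 and 4. On data simulated with the same dispersions and 200 genes changed, the fit recovered 0% of genes changed by 0.5 on the log2 scale, 43.8% at 1, 87.0% at 2 and 100% at 3, and 8 of its 119 calls were false. Recovery at an adjusted p depends on how many genes change. With 2456 genes called in the real data, these rates do not give the sensitivity of the real comparison.

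The design, the alternatives, 53 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members, 50 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance one way, were run beside it. For each described list, called members were also counted with p adjusted over the list alone. The 14 lists described at length were mesenchymal markers, extracellular proteases and inhibitors, targets of TGF-beta, collagens and basement membrane, airway secretory and goblet markers, epithelial junction and identity genes, gastrointestinal and hepatic lineage genes, interferon-stimulated genes, targets of NRF2, metallothioneins, cell adhesion immunoglobulins with CD44, BAF and PBAF subunits, the AP-1 family and alveolar type 2 markers.

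Named genes were SMARCA4, SMARCA2 and 9 other single genes, whatever their values. To these were added the 12 largest rises and the 12 largest falls among called genes with a group mean of at least 5 CPM and no overlap between groups, and the next 5 of lowest adjusted p in each direction. Up to 2 called members in each direction were named per described list. Of the genes taken by this rule, 1 of the 9 other single genes and 1 list member are not reported, for a reason unrelated to their values. Clone names, pseudogenes, XIST and chromosome Y were excluded.

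A fold against a group with no fragments was computed against a floor of 3 fragments over that group, and 1 to 3 fragments were given with an exact 95% counting interval of the ratio. Floors and intervals cover counting error only. Fragments without molecular identifiers are not independent molecules.

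Alternatives were DESeq2 size factors, library totals alone, no filter, a minimum of 1 CPM in 4 libraries, removal of abundant noncoding, mitochondrial and histone genes, 1 surrogate variable (sva 3.50.0), each library left out in turn, DESeq2 1.42.0, limma-voom, a gene length offset and an adjusted p under 0.01. Added after seeing the data were a GC content offset, subsets of 3 rescue libraries, pairs of libraries left out together, libraries with adjacent numbers summed and split anew as pairs, and the BAF list without SMARCA4. Computation used R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.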

Results

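Total RNA was sequenced from A549 cells whose SMARCA4 mutation had been corrected (rescue, 6 libraries) and from uncorrected cells (null, 4 libraries). The question, as the series states it, was what correction of the gene does to the regulatory landscape of these cells. The DNase I and CUT&RUN assays of the same project were not analysed here. Gene-assigned fragments numbered 3117497, 8670399, 9924375, 14308570, 6675393 and 14157133 in rescue libraries 1 to 6, and 6838522, 7878112, 12543970 and 7227273 in null libraries 1 to 4. Protein-coding genes took between 90.8% and 92.9% of them. Spike-in RNAs took between 1.48% and 5.71% of all fragments in rescue, and in null 0.9995%, 1.53%, 3.41% and, in null 4, 0.00956%. Correlation of log2 CPM across genes ranged from 0.923 to 0.986 within rescue, from 0.932 to 0.973 within null and from 0.865 to 0.933 between the groups. The first principal component of the 1000 most variable tested genes held 62.3% of their variance. It separated the groups, with rescue from 23.3 to 43.1 and null from -58.4 to -41.1. The labels do not say that the libraries came from separate cultures, so every p-value here measures only the spread between these libraries.

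SMARCA4 itself was higher in rescue. The gene (ENSG00000127616.17, GRCh38 chromosome 19, 10961001 to 11062282) stood at 85.2 ± 23.5 CPM (SD, n = 6) in rescue and 14.5 ± 1.34 CPM (SD, n = 4) in null, 5.85-fold higher. The lowest rescue library, at 55.7 CPM, lay above the highest null library, at 16.1 CPM. The log2 change was 2.55 with a standard error of 0.219 and an adjusted p of 2.92e-05. An exact two-sided permutation test gave p = 0.00952, the smallest that 210 splits allow. That test takes all 10 libraries as independent. If libraries with adjacent numbers are not, only 10 splits of 5 summed pairs exist, and 0.00952 is too small. SMARCA2 (ENSG00000080503.21, chromosome 9, 2015186 to 2193624), the alternative ATPase of the same complexes, stood at 128 ± 46.6 CPM (SD, n = 6) in rescue and 63.5 ± 7.5 CPM (SD, n = 4) in null, 2.01-fold higher, with an adjusted p of 0.0147. SMARCA2 was higher in all 6 rescue libraries than in any null library, and its exact permutation p was also 0.00952, with the same limit. The SMARCA2 call was lost without null 1, at an adjusted p of 0.0551, and with libraries of adjacent numbers summed, at 0.139, the highest of its alternatives, which reached down to 0.000867. Counts by gene do not show whether the SMARCA4 transcripts carried the corrected sequence.

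**Figure D1:**
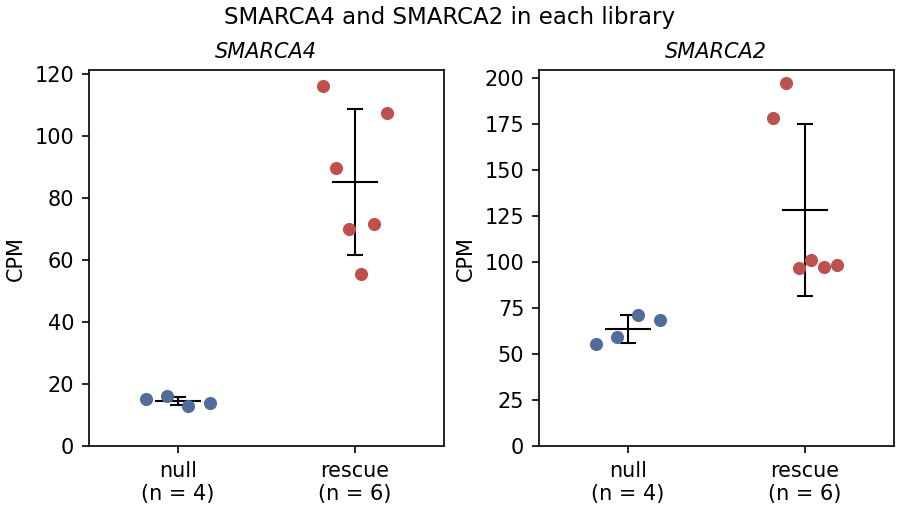
CPM of SMARCA4 and SMARCA2 (vertical axes) in the 4 null and 6 rescue libraries, with points for libraries, horizontal lines for means and bars for 1 SD. All 6 rescue points lie above all 4 null points for both genes, and the rescue mean of SMARCA4 is 85.2 CPM against 14.5 CPM in null.

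Of 14467 genes tested, 2456 (17.0%) were called, 1438 higher and 1018 lower in rescue. At least 2-fold changes made up 1285 of the calls, 817 higher and 468 lower. Protein-coding genes gave 1316 higher and 919 lower of 12299 tested, long noncoding genes 86 and 70 of 1100, and other genes 36 and 29 of 1068. The groups did not overlap in 1851 of the called genes, and in 14.7% of all tested genes against 0.952% by chance. That chance share holds only if the libraries are independent. If libraries with adjacent numbers are not, it is higher. Without null 1 the count was 1571 (948 higher, 623 lower), and with libraries of adjacent numbers summed it was 694 (404 higher, 290 lower, 599 at least 2-fold), of which 620 were among the 2456. With 1 surrogate variable as a covariate it was 3749, with 1663 lower.

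The largest rises were genes all but silent in null. HMCN1, which encodes the extracellular matrix protein hemicentin, stood at 67.0 ± 15.6 CPM (SD, n = 6) in rescue and 0.0897 ± 0.113 CPM (SD, n = 4) in null, 532-fold higher, with an adjusted p of 6.8e-07. DMBT1, a secreted scavenger receptor, stood at 175 ± 113 CPM (SD, n = 6) against 0.258 ± 0.19 CPM (SD, n = 4), 647-fold higher. Over the null libraries HMCN1 had 4 fragments and DMBT1 9, so both folds are rough. SPARC, a secreted matrix glycoprotein, stood at 469 ± 466 CPM (SD, n = 6) against 1.68 ± 0.545 CPM (SD, n = 4), with rescue libraries from 26.6 to 1106 CPM. ADAMTSL1 had no fragments in any null library and was at least 338-fold higher in rescue. With no null fragments either, IFI44L was at least 228-fold higher, the potassium channel gene KCNH5 at least 226-fold, PLPP4 at least 109-fold, TENM2 at least 82.8-fold, ACKR3 at least 60.1-fold, ARHGAP28 at least 56.1-fold and the prostaglandin receptor gene PTGFR at least 50.5-fold. These folds pool the rescue libraries, which differed. In rescue 5 and 6, TENM2 stood at only 0.45 and 0.29 CPM, ARHGAP28 at 0.75 and 0.0724 CPM and PTGFR at 0.75 and 0.51 CPM. In rescue 6, ARHGAP28 was too low to tell from null. RGS4, a regulator of G protein signalling, had 1 null fragment and a ratio of 720 (95% counting interval 129 to 28400). Floors and intervals cover counting error only.

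The largest fall was that of MGAM, a maltase-glucoamylase of the intestinal brush border. It stood at 0.123 ± 0.136 CPM (SD, n = 6) in rescue and 32 ± 16 CPM (SD, n = 4) in null, 205-fold lower. CPLX2, a regulator of vesicle fusion, stood at 10.5 ± 10.2 CPM (SD, n = 6) against 457 ± 331 CPM (SD, n = 4), 42.8-fold lower. CACNA1D, a calcium channel subunit, had 3 fragments over the rescue libraries and was 202-fold lower (95% counting interval 68.6 to 983). RBFOX3, a neuronal splicing factor, was 142-fold lower, IGSF11 67.4-fold, CYP4F3 57.3-fold, PARM1 39.5-fold, BCAS1 37.1-fold, CA8 36-fold and DEGS2 31.6-fold. Over the rescue libraries RBFOX3 had 5 fragments, MGAM 8 and DEGS2 9, so their folds are rough. CYP4F3 has near-identical copies, so its value is uncertain. Absence of overlap between the groups was a condition for naming these genes.

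Other genes without overlap between the groups followed by adjusted p. DLC1 stood at 74.5 ± 11.4 CPM (SD, n = 6) against 0.785 ± 0.323 CPM (SD, n = 4), 92.2-fold higher with an adjusted p of 2.15e-07. The antisense transcript TRHDE-AS1, with 5 null fragments, was 79.2-fold higher and SRPX 18.7-fold. FLI1, a transcription factor of the ETS family with 2 null fragments, had a ratio of 233 (95% counting interval 64.2 to 1930). Among the falls, the galactosyltransferase gene B4GALT4 stood at 48.7 ± 4.23 CPM (SD, n = 6) against 189 ± 22.1 CPM (SD, n = 4), 3.89-fold lower with an adjusted p of 2.4e-06. CA12, a carbonic anhydrase, was 5.36-fold lower, HILPDA, a lipid droplet protein induced by hypoxia, 5.19-fold, RASEF 4.29-fold and the actin-bundling gene PLS1 3.53-fold.

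Some of these calls were lost with fewer libraries or without the filter. The TENM2 call was lost without null 1, null 2, null 3 or null 4 (adjusted p of 0.0668, 0.0647, 0.0542 and 0.0568), with 1 surrogate variable (0.0729), by limma-voom (0.0877) and without the filter (0.16), over a range of 6.3e-06 to 0.16. ARHGAP28 was lost without null 1, null 2 or null 4 (0.0601, 0.0589 and 0.0507), with 1 surrogate variable (0.053), by limma-voom (0.106) and without the filter (0.144), over a range of 2.81e-05 to 0.144. PTGFR was lost without null 1 or null 2 (0.0566 and 0.0557) and without the filter (0.134), over a range of 6.58e-06 to 0.134. Without rescue 1 and null 4 together, TENM2, ARHGAP28 and PTGFR were also lost (0.0853, 0.0822 and 0.0772). These 3 genes failed the filter and were not tested without any of rescue 1 to 4 or without rescue 1 and 2 together, so the ranges leave those settings out. None of the 3 had a null fragment, so their folds have no upper bound and leaving out a null library could not show whether they moved. Without the filter ACKR3 reached 0.0907 (range 6.73e-09 to 0.0907) and IFI44L 0.0665 (range 1.25e-10 to 0.0797). Summing adjacent libraries, which leaves 3 against 2 samples, ended the calls of 22 named genes, of which 5 had no null fragments and the others had log2 changes 0.956 to 1.07 times those with all libraries: SMARCA2, CD44, VIM, IFI44L, TENM2, ACKR3, PTGFR, ARHGAP28, SPARC, CEACAM6, DEGS2, FGB, INHBB, LAMC3, COL4A4, CDS1, EHF, SAMD9L, AKR1B1, L1CAM, BATF3 and FOXA2. Leaving out 1 library moved the fold change of 10 of these and the list genes below by a factor over 1.5, with log2 changes going for CEACAM6 to -7.55 without rescue 6, CA8 to -5.97 without rescue 3, FGB to -5.66 without rescue 5, MMP2 to 6.91 without null 3 and SAMD9L to 3.96 without null 3. For the others of the 10 no value is given, since at most 1 fragment was left in the lower group: IFI44L without rescue 2, RGS4 without null 1, AFP without null 4, HMCN1 without null 3 and CACNA1D without rescue 4. Without rescue 1 and 2 together the change was 6.78 for SPARC and -5.78 for DEGS2, and without rescue 5 and null 3 together it was -6.12 for CPLX2. Another tool also moved folds. By limma-voom the log2 change was -7.79 for CEACAM6 (-6.21 by edgeR), -6.41 for FGB (-4.91), -6.45 for RBFOX3 (-7.15) and 7.18 for SPARC (8.14).

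Mesenchymal markers rose as a group in rescue. Of 24 tested members, 17 were higher, 0 lower and 7 not called, with a median log2 change of 1.80. SNAI2, a transcription factor that represses epithelial genes, stood at 22.4 ± 6.95 CPM (SD, n = 6) against 0.762 ± 0.311 CPM (SD, n = 4), 27.4-fold higher. CDH2, encoding N-cadherin, stood at 217 ± 36.5 CPM (SD, n = 6) against 62.3 ± 8.23 CPM (SD, n = 4), 3.49-fold higher. VIM, encoding the intermediate filament vimentin and named in advance, stood at 1678 ± 384 CPM (SD, n = 6) against 887 ± 242 CPM (SD, n = 4), 1.89-fold higher with an adjusted p of 0.0162 and with overlap between the groups. The camera adjusted p of the list was 1.48e-14, and 18 members were higher when adjusted over the list alone. The VIM call was lost without null 1, at an adjusted p of 0.0607 (range over its alternatives 0.000637 to 0.0619).

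Extracellular proteases and their inhibitors rose, with 12 higher, 0 lower and 10 not called of 22 and a median log2 change of 1.45. The membrane protease gene ADAM19 stood at 111 ± 13.4 CPM (SD, n = 6) against 11.8 ± 5.98 CPM (SD, n = 4), 9.32-fold higher. MMP2, a gelatinase, stood at 93.8 ± 50.8 CPM (SD, n = 6) against 1.44 ± 1.35 CPM (SD, n = 4), 58.6-fold higher. Targets of TGF-beta rose, with 11 higher, 1 lower and 14 not called of 26 and a median of 0.61. TGFBI, a secreted matrix protein, stood at 2666 ± 430 CPM (SD, n = 6) against 705 ± 74.8 CPM (SD, n = 4), 3.78-fold higher, and TNS1, a focal adhesion protein, was 25-fold higher. INHBB, an activin subunit, was 7.91-fold lower. Adjusted over the list alone, the counts were 15 higher and 3 lower for proteases and 13 higher and 3 lower for TGF-beta targets. Adjusted camera p-values were 6.37e-08 and 2.66e-07. The count of lower TGF-beta targets was 2 without rescue 5 or null 4 and 3 with 1 surrogate variable.

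Collagens and basement membrane genes gave 13 higher, 3 lower and 19 not called of 35, with a median log2 change of 1.07. COL5A1, a fibrillar collagen, stood at 617 ± 160 CPM (SD, n = 6) against 80.9 ± 43.9 CPM (SD, n = 4), 7.6-fold higher, and COL6A1 was 4.35-fold higher. COL4A4 was 3.54-fold lower and LAMC3, a laminin chain, 2.13-fold lower, both basement membrane genes at low levels. The list's camera adjusted p was 4.98e-07, and adjusted p = 0.161 with an estimated correlation. Adjusted over the list alone, 16 were higher and 3 lower. Without null 1, without the filter or without rescue 5 and null 3 together, 0 were called lower by edgeR, and without rescue 1, rescue 3 or null 2, 1 was. Without null 1 COL4A4 was at an adjusted p of 0.0922 and LAMC3 at 0.071, and without rescue 1 and 2 together the median was 0.58. COL4A4 was also lost without null 2, rescue 1 or rescue 3 (0.0572, 0.0549 and 0.0541) and without the filter (0.059), in a range of 0.0024 to 0.133, and LAMC3 without null 3 (0.0546) and without the filter (0.0663), in a range of 0.0137 to 0.135.

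Markers of fibroblasts, a cell type the labels do not name, moved with these groups. Of 8 tested members, 6 were higher, 0 lower and 2 not called, with a median log2 change of 3.39 and a camera adjusted p of 2.89e-05. The same 6 were the count adjusted over the list alone. The mesenchymal, collagen or protease lists also hold 4 of the 8. Without any 1 of the rescue libraries 6 were tested and 4 higher, with medians down to 2.42 (without rescue 2) and camera adjusted p up to 0.00151. Without rescue 1 and 2 together the median was 2.13, and without the filter it was 2.12. Endothelial markers had only 3 tested members, too few for a list test, but without the filter 15 were tested, with 2 higher, 0 lower, a median of 1.34 and a camera adjusted p of 0.0161, and with adjacent libraries summed 6 were, with 1 higher, a median of 1.29 and an adjusted p of 0.14. Neither was tested with an estimated correlation. Leukocyte markers gave 2 higher, 0 lower and 3 not called of 5, with an adjusted p of 0.44 by camera and 0.0345 by fry. Without rescue 4, null 1 or null 2, 0 were higher.

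Epithelial junction and identity genes fell as a group, with 2 higher, 11 lower and 16 not called of 29 and a median log2 change of -0.55. OCLN, encoding the tight junction protein occludin, stood at 9.75 ± 2.72 CPM (SD, n = 6) in rescue against 62.5 ± 26.7 CPM (SD, n = 4) in null, 6.43-fold lower. EPCAM, an epithelial adhesion molecule, was 5.63-fold lower. The exceptions were EHF, an epithelial transcription factor, at 65.4 ± 30.6 CPM (SD, n = 6) against 11.2 ± 8.55 CPM (SD, n = 4), and CDS1, 3.68-fold higher. CDH1, encoding E-cadherin and named in advance, stood at 34.9 ± 22.8 CPM (SD, n = 6) against 61.9 ± 20.1 CPM (SD, n = 4), with an adjusted p of 0.204. By camera the adjusted p was 2.13e-05, and 2 were higher and 14 lower when adjusted over the list alone. CDH1 passed without rescue 2, with a log2 change of -1.24 and an adjusted p of 0.0252 (range over alternatives 0.0252 to 0.428), and without rescue 1 and 2 together (0.0485). EHF was lost without the filter, at 0.0655 (range 1.84e-05 to 0.0981), without rescue 1 and null 4 together (0.069) and without rescue 1 and 2 together (0.0512).

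Airway secretory and goblet markers fell as a group, with 0 higher, 8 lower and 1 not called of 9 and a median log2 change of -2.47. SPDEF, a transcription factor of goblet cells, stood at 7.08 ± 2.89 CPM (SD, n = 6) against 23.2 ± 5.28 CPM (SD, n = 4), 3.21-fold lower. CEACAM6, which has close relatives with near-identical stretches and is uncertain, was 73.8-fold lower. The same 8 were lower when adjusted over the list alone, and camera gave an adjusted p of 1.83e-06. Gastrointestinal and hepatic lineage genes gave 1 higher, 8 lower and 9 not called of 18, with a median of -1.59. FGB, the fibrinogen beta chain, stood at 6.71 ± 7.75 CPM (SD, n = 6) against 198 ± 77.9 CPM (SD, n = 4), 30-fold lower, and VIL1, encoding villin, was 10.8-fold lower. AFP, encoding alpha-fetoprotein, had 2 null fragments and was higher, with a ratio of 68.5 (95% counting interval 18.7 to 569). Camera gave an adjusted p of 0.00351 for these genes, and adjusted p = 0.482 with an estimated correlation. Adjusted over the list alone, 1 was higher and 10 lower. Without the filter the median was -0.78, and without null 3 the count higher was 2.

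**Figure D2:**
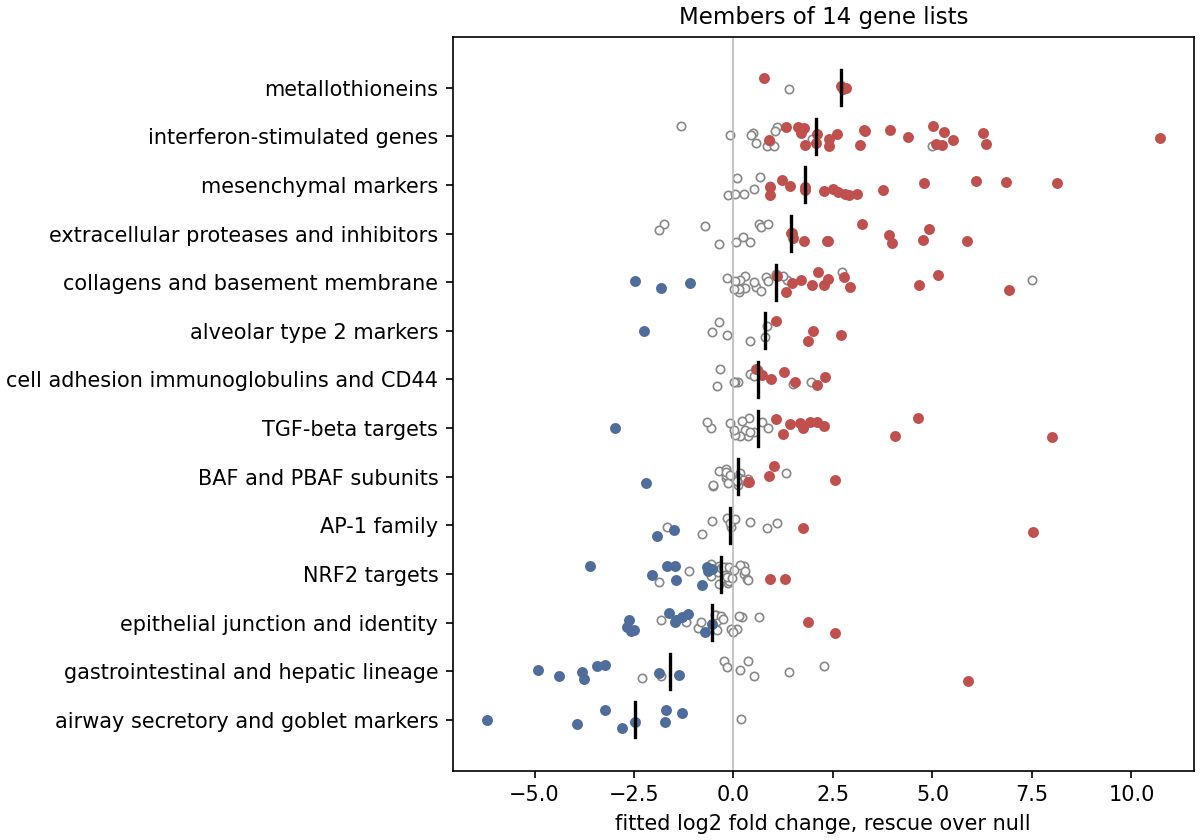
Fitted log2 fold change of rescue over null (horizontal axis) for the tested members of 14 gene lists, with filled red points for genes called higher, filled blue points for genes called lower, open points for genes not called and a black bar at each median. Mesenchymal markers have a median of 1.80 and airway secretory markers of -2.47.

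Interferon-stimulated genes were higher in rescue, at levels that differed widely among its libraries. Of 36 tested members, 24 were higher, 0 lower and 12 not called, with a median log2 change of 2.08. GBP1, an interferon-induced GTPase, stood at 13.2 ± 4.73 CPM (SD, n = 6) against 0.37 ± 0.261 CPM (SD, n = 4), 32.3-fold higher, and SAMD9L was 9.86-fold higher. The median CPM of the list was 49.1, 74.3, 20.8, 22.6, 9.58 and 10.1 in rescue 1 to 6 and between 5.47 and 7.63 in null. For the list, camera gave 4.15e-11 as adjusted p, and adjusted p = 0.474 with an estimated correlation, which was 0.785. Adjusted over the list alone, 27 were higher and 1 lower. Without rescue 1 and 2 together, 18 were higher and 1 lower of 34, with a median of 1.10, and with adjacent libraries summed 2 were called. The count was 12 without null 1 or null 2, 14 without null 4, 11 without rescue 1 and null 4 together and 10 of 44 without the filter.

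**Figure D3:**
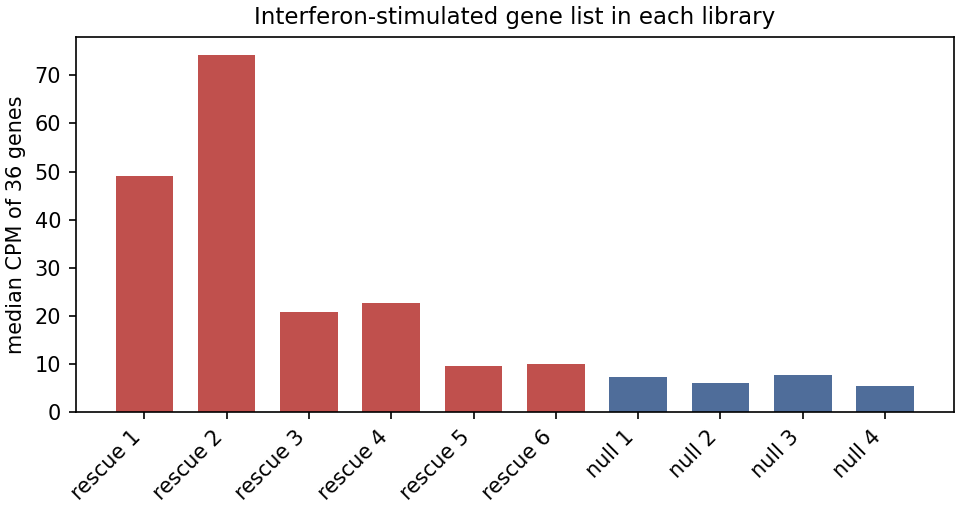
Median CPM of the 36 tested interferon-stimulated genes (vertical axis, from 0) in each library, with red bars for rescue and blue bars for null. Rescue 1 and 2 reach 49.1 and 74.3 CPM, rescue 5 and 6 reach 9.58 and 10.1 CPM, and the highest null library is at 7.63 CPM.

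Targets of NRF2, the regulator of antioxidant genes that is constitutively active in A549, gave 2 higher, 9 lower and 24 not called of 35, with a median log2 change of -0.31. GCLC, the catalytic subunit of glutathione synthesis, stood at 104 ± 26.0 CPM (SD, n = 6) against 332 ± 60.2 CPM (SD, n = 4), 3.18-fold lower, and PIR was 2.78-fold lower. AKR1B1 was 2.44-fold higher and EPHX1 1.89-fold higher. NFE2L2, which encodes NRF2, stood at 55.2 ± 9.11 CPM (SD, n = 6) against 75.2 ± 17.5 CPM (SD, n = 4), with an adjusted p of 0.0899, and KEAP1, its inhibitor, at 62.2 ± 9.37 against 70.8 ± 13.6 CPM, with an adjusted p of 0.446. Camera gave an adjusted p of 0.00126 for the targets, and adjusted p = 0.474 with an estimated correlation, with 2 higher and 12 lower when adjusted over the list alone. The median was -0.20 without null 2 and -0.17 without rescue 1 and 2 together, and 6 were lower without null 1 or null 2. Without null 2 or null 4, 1 was higher. EPHX1 was lost without null 2 or null 4 (adjusted p of 0.0811 and 0.0557) and with a GC content offset (0.058), in a range of 0.00377 to 0.0811, while NFE2L2 passed without rescue 5 or null 4 (0.0296 and 0.0355) and with 1 surrogate variable (0.0229), in a range of 0.0229 to 0.254.

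Metallothioneins and their zinc transporter gave 4 higher, 0 lower and 1 not called of 5, with a median log2 change of 2.70. MT2A stood at 336 ± 128 CPM (SD, n = 6) against 50 ± 23.4 CPM (SD, n = 4), 6.72-fold higher, and MT1X was 7.06-fold higher. Metallothionein genes are near-identical copies, so the division of fragments among them is uncertain. Camera gave an adjusted p of 0.000222, and adjusted p = 0.237 with an estimated correlation, and the same 4 were higher when adjusted over the list alone. Without null 2 or null 4, and without rescue 1 and null 4 together, the count was 2.

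Cell adhesion immunoglobulins with CD44 rose, with 7 higher, 0 lower and 10 not called of 17 and a median log2 change of 0.63. L1CAM, a neural adhesion molecule, stood at 24.1 ± 11.1 CPM (SD, n = 6) against 5.62 ± 0.782 CPM (SD, n = 4), 4.25-fold higher, and BCAM, a laminin receptor, was 2.4-fold higher. CD44, the hyaluronan receptor named in advance, stood at 429 ± 92.9 CPM (SD, n = 6) against 224 ± 54.7 CPM (SD, n = 4), 1.91-fold higher with an adjusted p of 0.00908 and all 6 rescue libraries above null. Tested by camera, the list had an adjusted p of 0.0012, and 9 were higher when adjusted over the list alone. Alveolar type 2 markers gave 4 higher, 1 lower and 6 not called of 11, with a median of 0.79. ACSL4, which activates arachidonic acid, was 3.98-fold higher, the cathepsin gene CTSH 3.66-fold higher and FOXA2, a lung and endoderm transcription factor, 4.74-fold lower. Camera gave an adjusted p of 0.0457, and adjusted p = 0.209 with an estimated correlation, with 5 higher and 2 lower when adjusted over the list alone. Without rescue 1, 2 were lower. That camera call was lost without rescue 1, rescue 2, rescue 4, null 2, null 3 or null 4 (adjusted p of 0.0567, 0.1, 0.0512, 0.0536, 0.0579 and 0.0739), in a range of 0.028 to 0.229 over all alternatives at the preset correlation, and the median was 0.51 without rescue 4. By fry the adjusted p was 0.00111.

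Of 27 tested BAF and PBAF subunits, 5 were higher, SMARCA4 and SMARCA2 among them, 1 lower and 21 not called, with a median log2 change of 0.11. SMARCD3 stood at 21.6 ± 3.31 CPM (SD, n = 6) against 11.7 ± 1.33 CPM (SD, n = 4), 1.84-fold higher. BCL11B, a lymphoid subunit, was 4.55-fold lower at a low level, 0.769 ± 0.359 CPM (SD, n = 6) against 3.72 ± 1.88 CPM (SD, n = 4). The camera adjusted p was 0.31 and that of fry 0.00937, and the counts were the same when adjusted over the list alone, 5 and 1. Without SMARCA4 in the list, 4 were higher and 1 lower of 26, with a median of 0.0977 and adjusted p of 0.699 by camera and 0.0714 by fry. The count higher was 2 without null 1 and 3 without null 2, null 3 or any of rescue 1 to 4, with library totals alone and without either pair of rescue 1 with rescue 2 or null 4. The count lower was 2 without rescue 5 and 3 with 1 surrogate variable.

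The AP-1 family moved in both directions, with 2 higher, 2 lower and 10 not called of 14. FOSL2 stood at 453 ± 150 CPM (SD, n = 6) against 136 ± 30 CPM (SD, n = 4), 3.33-fold higher. MAFK was 3.81-fold lower and BATF3 2.81-fold lower. The median log2 change was -0.08, the mean 0.35 and the camera direction up, with an adjusted p of 0.858. Adjusted over the list alone, 2 were higher and 4 lower. Without null 4, 4 were lower. Without null 1, 1 was, and BATF3 was lost at an adjusted p of 0.0713, in a range of 0.00542 to 0.0726.

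Of the other reported single genes named in advance, CDKN1A and STK11 did not pass, and CDKN2A was not tested. CDKN1A stood at 154 ± 52.6 CPM (SD, n = 6) against 145 ± 61.6 CPM (SD, n = 4), with an adjusted p of 0.888. STK11, a kinase known to be mutated in A549, stood at 37.7 ± 7.29 against 29.5 ± 6.4 CPM, with an adjusted p of 0.232. CDKN2A had 0 fragments in all 10 libraries. STK11 passed without rescue 5, with a log2 change of 0.46 and an adjusted p of 0.0476, in a range of 0.0476 to 0.503. The direction of CDKN1A turned with single libraries, to -0.13 without null 4.

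**Figure D4:**
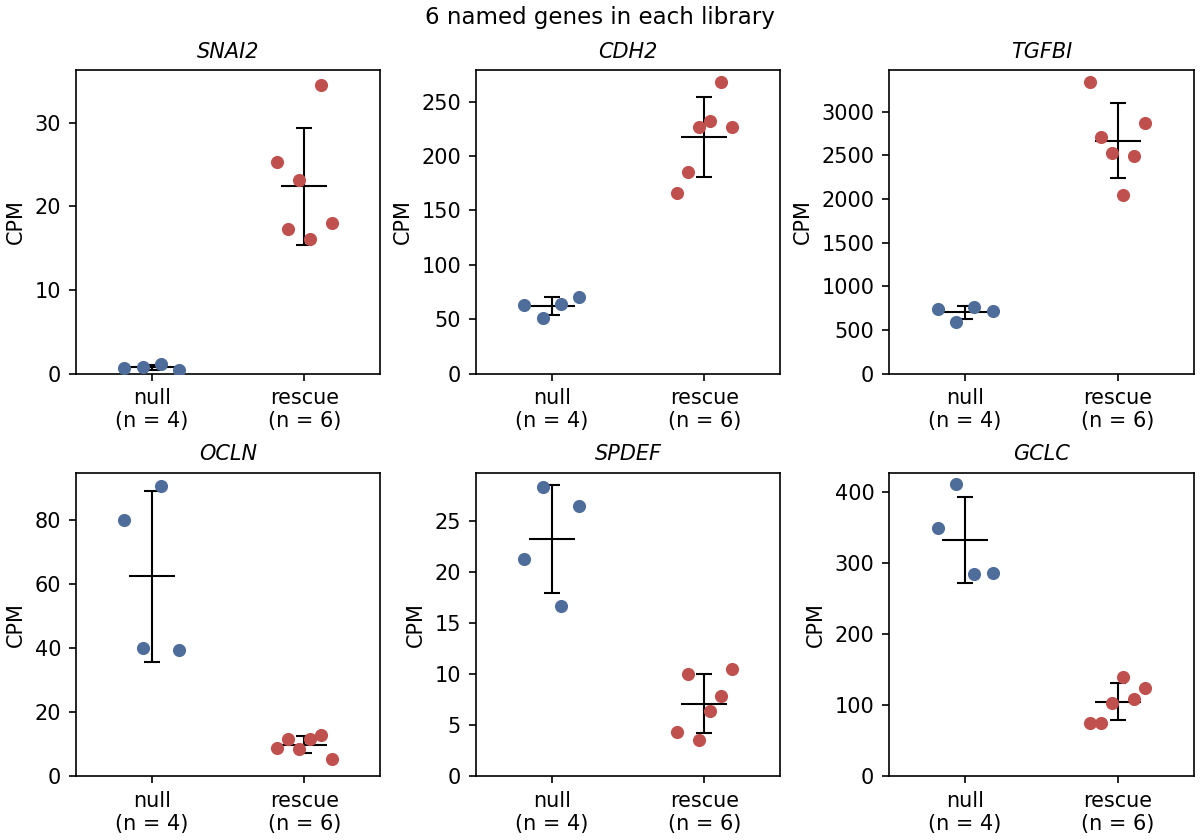
CPM (vertical axes) of SNAI2, CDH2, TGFBI, OCLN, SPDEF and GCLC in the 4 null and 6 rescue libraries, with points for libraries, horizontal lines for means and bars for 1 SD. The groups do not overlap for any of the 6 genes, with SNAI2, CDH2 and TGFBI higher and OCLN, SPDEF and GCLC lower in rescue.

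Of the 50 lists tested, 23 passed with the preset correlation, 14 upward and 9 downward. With an estimated correlation 8 held, mesenchymal markers (adjusted p of 0.000871), proteases (0.0399), TGF-beta targets (0.0399), ephrins and semaphorins (0.0399), airway secretory markers (0.0404), fibroblast markers (0.0404), epithelial genes (0.0484) and cell adhesion genes (0.0484). With adjacent libraries summed, the calls shrank to 7 higher mesenchymal markers, 6 higher proteases, 6 higher TGF-beta targets, 6 higher collagen genes, 3 higher fibroblast markers, 1 higher cell adhesion gene, 2 higher BAF subunits, 2 higher metallothionein genes, 6 lower epithelial genes, 3 lower airway markers, 2 lower gastrointestinal and hepatic genes and 4 lower NRF2 targets. List medians were the same to the digits given with silent genes placed at their bounds.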

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

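The tests of pairs of libraries, of a GC content offset, of dilution by other cells, of fibroblasts and of rescue 1 and 2 in the paragraphs below were chosen only after the results they concern were seen.

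The groups differed in 2456 genes. Chance is argued against if the 10 libraries are independent, since 1 of 100 splits of them into 6 and 4, the real one, called that many, and the highest other split called 3. If libraries with adjacent numbers are not independent, chance stays open, since only 10 splits of the 5 summed pairs into 3 and 2 exist, of which 1, the real one, called 694 genes and the others 0. Library size, gene length and GC content are argued against as the whole cause, since the library totals of the groups overlapped with a Spearman correlation of -0.00591 between change and mean level across genes, which are not independent replicates, and 2550 and 2414 genes were called with smooth length and GC offsets. A difference in library preparation as the whole cause is argued against among the other 9 libraries by the spike-in RNAs, of which edgeR called 0% of 55 with null 4 left out (4 at an unadjusted p under 0.05, no other tool run), while 2193 genes were called without it. Null 4 was left out because it held almost none (0.00956% of fragments), so this test says nothing about null 4. It also says nothing about steps before the spike-ins were added. Copy number of whole chromosomes as the whole cause is argued against by the 28.6% of calls on chromosomes whose median lay outside all 10000 random sets. These chromosomes had between 14.8% (chromosome 17) and 21.3% (chromosome 8) of their tested genes called, against 17.0% of all tested genes. Gained or lost segments need not move the median of a chromosome, so this test does not cover them. Differences between cultures or clones other than SMARCA4 stay open and untested, because the labels name neither, as does the effect of SMARCA4 itself.

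Mesenchymal markers rose and epithelial genes fell. Dilution by cells of another type stays open for the fall of the list as a whole. The 13 epithelial list members at 100 CPM or more in null had a median log2 change of -0.31 (-0.306), which differs from the -0.55 of the list by less than their SD of 0.608. Of the 13, 10 fell, from ELF3 at -1.63 to KRT19 at -0.02 (-0.02205), with the abundant KRT18 at -0.25 (-0.2508), uncalled. KRT81, KRT8 and KRT7 rose, at 0.65 (0.6476), 0.21 (0.211) and 0.09 (0.09135), all uncalled. An even fall of all 13, which dilution by cells without these transcripts would give, was therefore not seen. ELF3, the lowest of the 13, fell less than OCLN (-2.68) and EPCAM (-2.49). This argues against such dilution as the whole cause of the falls of OCLN and EPCAM. The comparison of medians cannot decide how much dilution contributed to the list. Fibroblasts mixed into the rescue cultures are argued against for the rise, since COL1A1, COL1A2, COL3A1, DCN and LUM together reached at most 3.34% of the rise of FN1, and COL1A2 and DCN, abundant in fibroblasts, stayed at most at 0.654 and 0.692 CPM. Clonal differences and the effect of SMARCA4 stay open and untested.

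Interferon-stimulated genes were highest in rescue 1 and 2. An origin in those libraries alone is argued against, since without them the median log2 change of the list was 1.10. The interferon genes of the 6 rescue libraries fell into levels shared by libraries with adjacent numbers, which leaves a difference between cultures or clones open. No test here separates that from the effect of SMARCA4.

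Of 168 groups of values, 156 for named genes and 12 for library measures such as totals, 6 had a library far from the rest, against about 8.4 by chance (about 1 in 20). Each distance is the gap to the nearest library over the range of the group on the log2 scale, after adding 0.5 CPM. Groups without a fragment in any library count among the 168 but could not be flagged, so 8.4 is somewhat high. NFE2L2 was highest in rescue 5 (0.73), at 73.5 CPM against at most 54.6 CPM in the other rescue libraries. STK11 was lowest in rescue 5 (0.879), at 22.9 CPM against at least 39.3 CPM. RGS4 was highest in null 1 (1), at 0.142 CPM with 0 in the other null libraries. AFP was highest in null 4 (1), at 0.28 CPM with 0 in the others. For RGS4 and AFP the distance was bound to be 1, since every other null library was at 0. BCAS1 was lowest in null 4 (0.954), at 14.3 CPM against at least 15.9 CPM, and SMARCD3 was highest in null 3 (0.888), at 13.7 CPM against at most 11.2 CPM.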

How the results depend on the processing

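The GC content offset, the subsets, the paired leave-outs and the summed libraries were chosen only after the results were seen. SMARCA4 kept its direction and its call under all 24 alternatives, with log2 changes from 2.40 to 2.66 and adjusted p up to 0.0127. No called gene turned its sign in any of the 24 alternatives or the 20 subsets of 3 rescue libraries that tested it. Of 77 other named genes, 61 kept direction and side of the threshold under the alternatives set in advance and 50 under all, and of 50 lists 16 and 15. The count of 2456 was 3209 with DESeq2 (2446 shared), 2456 with limma-voom (2271 shared), 3749 with 1 surrogate variable (1663 lower), 1079 at an adjusted p under 0.01, 1781 without rescue 1 and null 4, 1777 without rescue 1 and 2, 2788 without rescue 5 and null 3, and 694 with adjacent libraries summed (404 higher, 290 lower, 599 at least 2-fold), which leaves 3 against 2 samples. Subsets of 3 rescue libraries gave 796 to 2064, with 598 of the calls in all 20 subsets and 261 in none. Leaving out 1 library gave 1571 (without null 1) to 2931 (without rescue 5), with 948 to 1599 higher and 623 to 1332 lower. Turned directions, none past the threshold on either side, were, as log2 changes or list medians (a list's direction is that of its test): CDKN1A -0.0138 (GC offset), -0.16 (without rescue 1 and null 4) and -0.12 (without rescue 1 and 2); AP-1 -0.0587 (surrogate variable), -0.15 (GC offset), -0.162 (without rescue 1 and null 4) and 0.102 (summed); neuroendocrine markers 0.375 (no filter), 0.283 (GC offset) and 0.294 (summed); small noncoding RNA 0.0463 (GC offset) and -0.013 (without rescue 1 and 2). Squamous markers gave 0.209 and G1/S genes 0.00722 without rescue 1 and null 4, glucocorticoid-responsive genes 0.0446 and leukocyte markers -0.341 without rescue 1 and 2, G2/M genes 0.0578 and MAPK targets 0.00115 without rescue 5 and null 3, and Polycomb subunits 0.0609 by fry. Leaving out 1 library, directions turned within CDKN1A -0.13 to 0.33, AP-1 -0.142 to 0.225, G1/S -0.501 to 0.0435, G2/M -0.101 to 0.435, MAPK -0.182 to 0.0661, Polycomb -0.0243 to 0.0719, small noncoding 0.0206 to 0.143, glucocorticoid -0.125 to 0.254 and leukocyte -0.242 to 0.118. The cause was not tested. Depth limits genes near the floor, where 1 fragment in rescue 1 stood for 0.321 CPM before TMM scaling.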

Other observations

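The tests of adjacent libraries, of summed libraries and without rescue 5 and null 3 below were chosen only after the results were seen, as were the genes named in this part, apart from those of the naming rule.

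Several gene groups beyond those described moved between rescue and null. Ephrins and semaphorins rose, with 8 higher, 0 lower and 17 not called of 25, a median log2 change of 0.44 and a camera adjusted p of 0.000615 (13 higher and 1 lower adjusted over the list alone). The receptor gene EPHA4 stood at 106 ± 48.7 CPM (SD, n = 6) in rescue against 4.68 ± 1.01 CPM (SD, n = 4) in null. Complement and coagulation genes gave 10 higher, 2 lower and 11 not called of 23, with a median of 0.71, an adjusted p of 0.00944 and adjusted p = 0.482 with an estimated correlation (10 higher and 4 lower adjusted over the list alone). C3 stood at 494 ± 402 CPM (SD, n = 6) against 31.8 ± 8.56 CPM (SD, n = 4) and CFI was 33.6-fold higher, while CLU fell by 1.27 on the log2 scale. The complement median was 0.33 without rescue 2 and 0.42 without null 2, with 6 higher without null 2. Glycolysis enzymes gave 5 higher, 0 lower and 13 not called of 18, with a median of 0.40, an adjusted p of 0.000222 and adjusted p = 0.435 with an estimated correlation (5 higher adjusted over the list alone, and a median of 0.24 (0.245) without null 3). The lactate transporter gene SLC16A3 was 7-fold higher and HK1 2.73-fold higher. MHC class I genes gave 6 higher, 0 lower and 11 not called of 17, with an adjusted p of 0.00181 and adjusted p = 0.474 with an estimated correlation (9 higher adjusted over the list alone), and B2M was 1.92-fold higher. Targets of YAP and TEAD gave 7 higher and 2 lower of 26, with an adjusted p of 0.000769 and adjusted p = 0.248 with an estimated correlation (7 and 2 adjusted over the list alone, and a median of 0.28 (0.275) that was 0.46 without null 1). The count lower was 1 without any single library other than rescue 3.

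Other groups moved in both directions without passing as lists by camera. Ligands and receptors of the EGF family gave 1 higher and 4 lower of 13 (adjusted p of 0.261), with ERBB3 changed by -2.93, AREG by -2.58 (-2.575) and EREG by -1.21 on the log2 scale, and EGF 5.52-fold higher. NF-kB and inflammatory targets gave 5 higher and 3 lower of 25, with a median of -0.01, a mean of 0.63 and an adjusted p of 0.717. As single libraries were left out, their count lower ranged from 1 (without rescue 6) to 4. IL33 was 141-fold higher, IL6 58.1-fold and CXCL1 7.84-fold, and PTGS2 fell by 2.87 on the log2 scale. Median and mean or test also differed in sign for hypoxia targets (median 0.12, mean 0.01, test down), glucocorticoid-responsive genes (0.09, -0.13, down), MAPK targets (-0.08, 0.05, down), leukocyte markers (-0.00308, 0.475, up) and Polycomb subunits (0.06, 0.01, down), none past the threshold by camera, while leukocyte markers had an adjusted p of 0.0345 by fry. Targets of WNT gave 7 higher and 2 lower of 19 (adjusted p of 0.116 by camera and 0.013 by fry), with WNT5A at 23.5 ± 17.3 CPM (SD, n = 6) against 0.16 ± 0.125 CPM (SD, n = 4). Their count lower was 1 without rescue 3, rescue 5, rescue 6, null 1 or null 2.

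Cell cycle genes differed between libraries within each group. Of 37 genes of G2/M and 39 of G1/S, edgeR called 0, with 1 and 0 at an unadjusted p under 0.05, 1 and 0 called by DESeq2 and 0 and 0 by limma-voom. With 1 surrogate variable 12 G2/M genes were higher and 1 lower, with a camera adjusted p of 0.00128, and 4 G1/S genes were higher and 2 lower. G1/S genes passed downward by camera without null 3 (median log2 change of -0.501, adjusted p of 0.00405) and without rescue 5 and null 3 together (-0.34, 0.0453). These camera calls used the preset correlation. With all libraries and no covariate, the estimated correlation was 0.956 for G2/M and 0.829 for G1/S genes. Camera with it gave an adjusted p of 0.92 for each. The median log2 difference of these genes from each gene's mean was -1.72 in null 3 and -1.17 in rescue 5, against 0.73 (0.725) in null 2 and 0.76 in rescue 3. Without rescue 5 and null 3 together 2788 genes were called, 2102 of them among the 2456. Cytosolic ribosomal proteins gave 0 calls of 55 by edgeR (6 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom) with a median of -0.21, and as a list they passed downward by camera, at an adjusted p of 0.0113. That call was lost without null 3 (median of -0.0615, adjusted p of 0.464), without rescue 5 and null 3 together (0.334), without rescue 1 and 2 together (0.0982), with an estimated correlation (0.739) and by fry (0.237).

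Some libraries with adjacent numbers resembled each other. By correlation of log2 CPM the closest library had the adjacent number in rescue 1 to 5 and null 1 and 2, but rescue 6 was closest to rescue 4 (0.977), null 3 to null 1 (0.957) and null 4 to null 2 (0.969), and null 3 with null 4 reached 0.944. Of 15 genes at 5 CPM or more in exactly 2 rescue libraries and under 0.5 CPM in the others, 100% were on in an adjacent pair, against 20% by chance, with 13 in rescue 1 and 2. All 17 such null genes were on in an adjacent pair, 16 of them in null 3 and 4. This is consistent with libraries that came in pairs from shared cultures or clones, a hypothesis the labels neither state nor exclude. If it holds, the independent samples are fewer than the libraries, and the count with adjacent libraries summed was 694.

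Neighbouring genes tended to change together. Across 14406 pairs of adjacent tested genes, which are not independent replicates, the Spearman correlation of their log2 changes was 0.177, above all 10000 shuffles of gene order (-0.0128 to 0.0482, p = 1e-04, the smallest such shuffles can give in this permutation test). It was 0.181 for genes under 0.1 Mb apart, 0.06 for those 0.1 to 1 Mb apart and 0.0296 for those 1 to 5 Mb apart. This argues against gained or lost segments of several Mb as the whole cause of the correlation. Segments shorter than 1 Mb, or a few longer ones, are not covered by this test over the whole genome. Coordinated change of neighbourhoods may account for the correlation, and related genes in tandem were not separated. Around SMARCA4, 4 of 49 tested genes within 1 Mb were called, with a median of 0.05. Medians outside all 10000 random sets were found on chromosomes 5 (-0.20), 8 (-0.12), 11 (0.06), 12 (0.08), 17 (0.04) and X (0.07). By adjusted p against these sets, chromosomes 9 (-0.10), 13 (-0.135) and 16 (-0.087) also passed, each at 0.00102, as did 22 (0.00828) and 6 (0.033). The sets draw genes singly although neighbours correlate, so they vary too little. A copy change of chromosome 5 or of another of these stays open.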
